A study of Mus musculus with 27 samples.

How the data were processed

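Liver, brain and bone marrow of mice carrying a knockout-first allele of Mysm1 were profiled on Illumina BeadChips. Each of the 3 tissues had 3 genotypes (wild type, heterozygous and homozygous), and each of the 9 groups had 3 arrays, 27 arrays in all. Per the labels, 1 array held total RNA from 1 tissue sample, and the series' design text says that the tissue comparisons are between animals, so arrays of a group were taken as separate animals. Whether arrays of different tissues came from the same animal was not stated in the sources used here.

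The deposited table of scanner values held, per the file headers, a mean signal, a standard error over beads, a bead number and a detection p-value for each probe. The signals are intensity values on a linear scale; per the submitters' processing notes they came from BeadStudio, whose version and background setting are not given in the sources used here. The array medians of the deposited intensity values differed and none lay near 0, so these signals had not been normalised between arrays or background-subtracted. The deposited detection p-value moved in steps of 1/936, the step a comparison with that many negative control values gives. The deposited bead number, another kind of value, had a median of 43.0 to 45.0 beads per probe on every array. A second deposited table held processed intensity values, also linear, for the same 45281 probes. Per the submitters' processing notes limma was used, and the step is not given in the sources used here. The values lay within 2.24% of a quantile normalisation of the linear signals over all 27 arrays, and each of the 27 columns correlated best with its own scanner column, so scale and arrangement were settled. The column medians lay between 85.4 and 85.6. No columns of other samples were in either table.

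Gene names came from the platform annotation. Of the 45281 probes, 34885 had 1 gene symbol, 18 had several and 10378 had none; 34807 of the probes with 1 symbol matched a mouse RefSeq gene (table of assembly GRCm38.p6) by Entrez identifier, and 0 symbols needed updating. No gene was named from a probe with several symbols, and probes with none were tested under their probe identifiers. The genome build behind the probe annotation is not given in the sources used here, so no coordinates are printed.

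Signals were background-corrected with limma's neqc (normexp fitted to the negative control level inferred from the detection p-values, offset 16), quantile-normalised over the 9 arrays of a tissue and taken to log2. Probes with a detection p below 0.05 on at least 3 of the 9 arrays were kept, and the probe with the highest mean stood for a gene. This left 11745 features in liver (9590 named genes), 14423 in brain (11429 named genes) and 11507 in bone marrow (9153 named genes). Levels below are means of these log2 intensities with the SD over arrays. Each tissue was fitted with lmFit and eBayes (limma 3.58.1, R 4.3.3) over its 3 genotypes, which share 1 estimate of the spread per feature. The 3 genotype pairs were tested two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Errors of differences are standard errors of the fit. Where a gene was undetected on every array of its dimmer group, the fold is a lower bound: the bright group's mean against the dim group's mean of, per array, the higher of the lowest detected signal and the gene's own signal. The number of arrays limits the precision given here.

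Differences between tissues in the homozygous against wild-type effect, and an effect shared by the tissues with BeadChip as a term, were fitted over all 27 arrays after neqc over all of them (17374 features). In these joint fits the tissues share 1 spread per feature. The 55 gene lists (pathways, complexes, cell types and control genes) were tested with limma's camera at a preset correlation of 0.01 where at least 5 members were measured, with Benjamini-Hochberg adjustment within a tissue. The same test with an estimated correlation, and limma's fry, were run beside it. The lists, the comparisons, the filters and the rule for named genes were chosen before the data were examined.

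The named genes are, per tissue, the 10 highest and 10 lowest log2 changes of homozygous against wild type among named genes past the threshold whose groups did not overlap, and the 3 highest and 3 lowest for the other genotype pairs. For each tissue difference they are the 5 smallest p-values past the threshold, and for the shared effect the 5 smallest in each direction. For each gene list they are up to 4 members with the smallest p past the threshold or, where no member passed, the 2 with the smallest p. Mysm1 (every probe) and the control genes Xist, Eif2s3y, Kdm5d, Ddx3y and Nnt were fixed as well. Genes named outside these rules are said to be.

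Group and BeadChip were linked. The 5 BeadChips held wild-type and heterozygous livers (the first), homozygous livers and wild-type brains (the second), heterozygous and homozygous brains (the third), wild-type and heterozygous bone marrow (the fourth) and the bone marrow arrays labelled homozygous (the fifth). Homozygous against wild type therefore crossed BeadChips in every tissue, and BeadChip and genotype cannot be told apart there. Heterozygous against wild type lay within 1 BeadChip in liver and bone marrow, and homozygous against heterozygous within 1 in brain.

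The fits were tested on simulated data with known changes drawn from the real means and spreads. For homozygous against wild type, 2-fold changes were recovered in 78.5% of cases in liver, 84.9% in brain and 22.5% in bone marrow, and 4-fold changes in 98.0%, 98.9% and 80.2%. For the joint fits, simulated with each tissue's own spread and no effect, a mean of 53.4 features was called for bone marrow minus liver, 56.0 for bone marrow minus brain and 0.2 for liver minus brain. Recovery of 2-fold changes in the joint fits was 18.2%, 19.1% and 20.3%, and 29.0% for the shared effect. The recovery runs used 1 spread per feature pooled over the 9 groups, so they do not describe each tissue's own scatter.

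The alternatives tried were other background corrections and normalisations, the deposited processed values, other detection filters, every probe, other array sets in a fit, array weights, another eBayes setting, the replicate number as a block, a fold minimum and the omission of each array. Alternatives chosen after seeing the data were array brightness as a covariate in bone marrow, omission of the 4 bone marrow arrays with a raw mean signal under 110, and the first residual component as a covariate in brain. Embryonic fibroblasts and embryonic stem cells, which the design text also mentions, were not analysed here.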

Results

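The series asked how loss of Mysm1, a histone H2A deubiquitinase, alters gene expression in mouse tissues. Transcript levels were measured in liver, brain and bone marrow of wild-type mice and of mice heterozygous or homozygous for a knockout-first allele, on a C57BL/6 background, with 3 arrays in each of the 9 groups. The mean raw signal per array lay between 281.9 and 361.0 in liver and between 285.3 and 372.8 in brain. Bone marrow arrays were dimmer and less even: the wild-type mean was 186.33 ± 46.63 (SD, n = 3), the heterozygous mean 113.37 ± 18.79 and the mean of the arrays labelled homozygous 110.53 ± 23.87. Probes detected above background made up 34.7%, 33.7% and 33.6% of all probes in wild-type, heterozygous and homozygous liver, 43.7%, 43.7% and 43.6% in brain, and 32.3%, 25.7% and 24.8% in bone marrow. Arrays of 1 genotype correlated across genes at 0.984 to 0.991 in liver and 0.986 to 0.994 in brain, against 0.968 to 0.990, 0.948 to 0.954 and 0.802 to 0.918 for bone marrow labelled wild type, heterozygous and homozygous.

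Mysm1 itself fell in homozygous liver and brain. Its 1 clearly detected probe (ILMN_3119954) read 7.49 ± 0.17 (log2 intensity, SD, n = 3) in wild-type liver, 6.55 ± 0.08 in heterozygous liver and 4.80 ± 0.37 in homozygous liver, where 1 of 3 arrays detected it. The homozygous livers were 6.42-fold below wild type (limma adjusted p = 9.95e-05) and 3.37-fold below heterozygotes (limma adjusted p = 0.00166). In brain the same probe read 8.35 ± 0.07, 7.68 ± 0.13 and 6.42 ± 0.05 in wild type, heterozygotes and homozygotes, a fall of 3.82-fold against wild type (limma adjusted p = 5.31e-05) and 2.40-fold against heterozygotes (limma adjusted p = 0.00242). Heterozygotes lay between the other genotypes on every array of both tissues, at -0.93 ± 0.17 in liver and -0.67 ± 0.09 in brain against wild type, without passing the test over all genes (limma adjusted p = 0.291 and 0.193).

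In bone marrow the Mysm1 probe did not separate the genotypes. Wild-type arrays read 6.18, 6.29 and 6.4, heterozygous arrays 6.35, 6.08 and 6.35, and the arrays labelled homozygous 6.48, 4.88 and 6.95, so 2 of these 3 lay above the wild-type mean of 6.29. The array at 4.88 also carried strong liver transcripts, given with the bone marrow lists. The difference of -0.18 ± 0.43 did not pass the test (limma adjusted p = 0.793). Mysm1 therefore does not bear out the homozygous label of 2 bone marrow arrays, and the bone marrow groups are named here by their labels. Xist in bone marrow read 8.08 ± 0.07 in wild type, 8.42 ± 0.87 in heterozygotes and 7.07 ± 0.62 on the arrays labelled homozygous, with unadjusted p = 0.0372 against wild type and 0.00896 against heterozygotes (limma adjusted p = 0.16 and 0.183). A second Xist probe (ILMN_1224091), detected on every bone marrow array, read 7.77 ± 0.17, 7.89 ± 0.84 and 6.13 ± 0.65, a larger fall. Nnt read 4.87 ± 0.10, 5.41 ± 0.12 and 5.73 ± 0.86 there (unadjusted p = 0.0358 for arrays labelled homozygous against wild type, limma adjusted p = 0.158). Before scaling, the mean signal of the Mysm1 probe ILMN_3119954 over background was 111.9 in wild-type, 37.5 in heterozygous and 24.6 in the bone marrow arrays labelled homozygous. Of the other Mysm1 probes, ILMN_2717487 and ILMN_3044588 stayed at background in liver and brain. ILMN_1217271 was at background in liver and read 5.54 ± 0.13, 5.03 ± 0.37 and 4.71 ± 0.16 in wild-type, heterozygous and homozygous brain, a difference of -0.83 between homozygotes and wild type that did not pass the test (limma adjusted p = 0.607). Where these probes lie relative to the trapped part of the gene is not given in the sources used here.

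**Figure D1:**
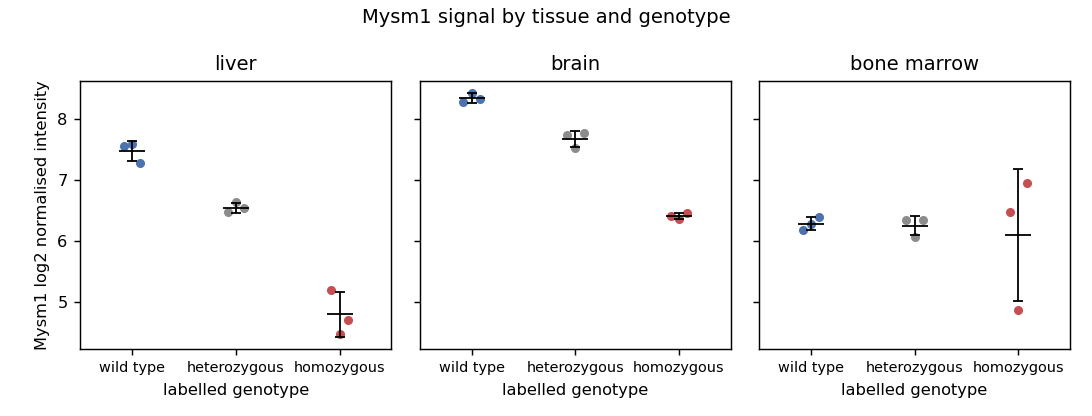
Mysm1 signal (log2 normalised intensity, vertical axis) of each array by tissue and labelled genotype, with group mean and SD (n = 3). Homozygous liver (mean 4.80) and brain (6.42) lie below wild type (7.49 and 8.35), while bone marrow arrays labelled homozygous spread from 4.88 to 6.95 around the wild-type mean of 6.29.

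The comparison of homozygous with wild-type liver asked which liver transcripts follow loss of Mysm1. Genes known for higher expression in male than in female mouse liver rose. Cyp4a12a, a fatty acid hydroxylase, read 10.35 ± 0.86 in homozygotes and 5.24 ± 0.41 in wild type, where 2 of 3 arrays detected it (mean log2 ± SD, n = 3 each; 34.5-fold, limma adjusted p = 0.000499). Hsd3b5, a hydroxysteroid dehydrogenase, rose by 4.31 ± 0.44 on the log2 scale (19.9-fold), Cyp4a12b by 3.91 ± 0.31 (15.0-fold over a wild-type signal hardly above background, detected on 1 of 3 arrays) and Cyp2d9, a testosterone hydroxylase, by 3.11 ± 0.39 (8.61-fold). The fatty acid elongase Elovl3, the urinary pheromone proteins Mup20 and Mup21, the oxysterol hydroxylase Cyp7b1, the complement component C6 and the selenium-binding protein Selenbp2 rose between 4.52-fold and 6.70-fold. Genes known for higher expression in female liver fell. The hydroxysteroid sulfotransferase Sult2a2 went from 11.43 ± 0.38 in wild type to 4.89 ± 0.21 in homozygotes, where 1 of 3 arrays detected it (log2 change -6.54 ± 0.55, limma adjusted p = 0.000499).

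Further genes that fell in homozygous liver were the cytochrome P450 genes Cyp2b13 (-4.44 ± 0.57, 21.7-fold) and Cyp2b23 (-2.44 ± 0.44), the steroid hydroxylase Cyp17a1 (-2.48 ± 0.35), the plasma glycoprotein gene A1bg (-3.10 ± 0.41), the hepcidin gene Hamp2 (-3.31 ± 0.58), the acyl-CoA thioesterase Acot3 (-2.42 ± 0.48), the transporter Slc22a26 (-2.39 ± 0.45) and Mysm1 itself. Sybu, which encodes a kinesin adaptor, fell at least 3.35-fold, with homozygous arrays not above background; its other measured probe read -0.44 and did not pass the test (limma adjusted p = 0.649). Second probes of C6 and A1bg passed the test in the same direction. Several of these genes (Cyp4a12a, Cyp4a12b, the Mup and Cyp2b genes) belong to families of closely similar members, and probe specificity was not tested here.

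By limma, 167 of the 11745 liver features passed, 78 higher and 89 lower in homozygotes; 138 of them were named genes and 154 changed by at least 1.5-fold. The groups did not overlap for 2775 features (23.6%, against 10% by chance). The homozygous livers lay on another BeadChip than the wild-type livers. For liver homozygous vs wild type the count was 46 without homozygous replicate 2, 56 without homozygous replicate 1, and 87, 50 and 105 without wild-type replicates 1, 2 and 3. It was 385 with array weights.

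Among the fixed lists, 17 of 22 measured male-biased liver genes rose, 0 fell and 5 did not pass (median log2 change 2.03). Adjusted over the list alone, 20 were higher and 1 lower. Their call by camera (limma adjusted p = 2.61e-27) was lost at adjusted p = 0.103 with an estimated correlation. Of 14 measured female-biased liver genes, 8 fell, 0 rose and 6 did not pass (median -2.03; 9 lower when adjusted over the list alone). Camera gave a limma adjusted p of 1.56e-11, and adjusted p = 0.103 with an estimated correlation. Xist, the X-inactivation transcript of female cells, was detected on all 9 liver arrays at 9.26 ± 0.17 in wild type, 9.40 ± 0.83 in heterozygotes and 9.16 ± 0.69 in homozygotes (limma adjusted p = 0.929 for homozygotes against wild type). Of the genes on the Y chromosome, Kdm5d was detected on none of these arrays. Eif2s3y read 4.67 ± 0.16, 4.95 ± 0.22 and 4.69 ± 0.22, near background, and was detected on 2 heterozygous and 1 homozygous arrays. Of 4 probes of Uty, looked at after its values were seen, 1 was detected on 2 wild-type and 1 homozygous liver arrays (4.89 ± 0.27, 4.59 ± 0.26 and 4.72 ± 0.19) and on all 9 brain arrays. The sex of the mice is not stated in the sources used here. In homozygous liver Nnt, part of which is deleted in the C57BL/6J substrain, read 5.02 ± 0.25 against 5.31 ± 0.22 in wild type. Where its probe lies relative to that part is not given in the sources used here.

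**Figure D2:**
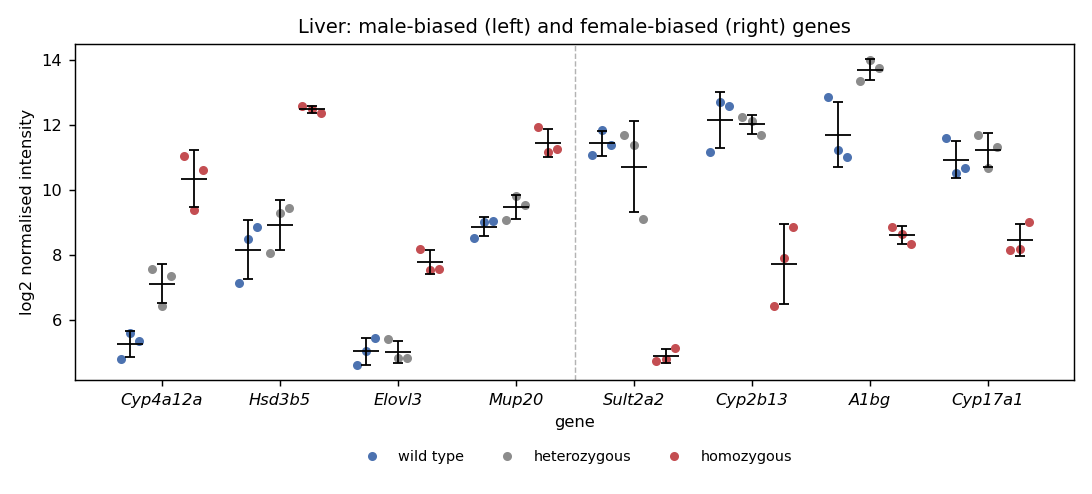
Log2 normalised intensity (vertical axis) on each liver array for 4 male-biased genes (left) and 4 female-biased genes (right), with mean and SD per genotype (n = 3). Cyp4a12a means run from 5.24 in wild type to 10.35 in homozygotes and Sult2a2 means from 11.43 to 4.89, with 7.10 and 10.72 in heterozygotes.

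Interferon-stimulated genes were lower in homozygous liver as a list. The guanylate-binding protein gene Gbp2 fell by 0.81 and the antiviral gene Ifit3 fell by 0.84 on the log2 scale, the other 28 of 30 did not pass, and 16 were lower when adjusted over the list alone (median -0.39; camera, limma adjusted p = 3.79e-08; adjusted p = 0.156 with an estimated correlation). Of 18 fatty acid synthesis genes, 4 fell and 1 rose. The lipogenic regulator Srebf1 (-1.21 ± 0.16), ATP citrate lyase Acly (-0.99 ± 0.14) and acetyl-CoA carboxylase Acacb (-0.78 ± 0.12) fell, while Elovl3, which also stands in the male-biased list, rose. Adjusted over the list alone, 5 were lower and 1 higher (median -0.42; camera, limma adjusted p = 6.87e-05; adjusted p = 0.416 with an estimated correlation). Of 37 xenobiotic metabolism genes, 4 cytochrome P450 genes fell (Cyp2a4, Cyp2b9, Cyp2b13 and Cyp2c39), 0 rose and 33 did not pass. Of these, Cyp2a4, Cyp2b9 and Cyp2b13 also stand in the female-biased list. Adjusted over the list alone 7 were lower and 1 higher (median -0.15; camera, limma adjusted p = 0.00962; adjusted p = 0.439 with an estimated correlation).

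Several cell type lists were lower in homozygous liver. No member of the hepatic stellate and fibrosis list passed, with 11 of 12 values negative, such as -0.76 ± 0.21 for the filament gene Vim and -0.75 ± 0.24 for the collagen gene Col1a1 (median -0.40; camera, limma adjusted p = 0.00193; adjusted p = 0.241 with an estimated correlation). Heterozygous liver had a median of -0.42 for this list. Of 17 endothelial genes 0 passed (median -0.21; camera, limma adjusted p = 0.00962; adjusted p = 0.439 with an estimated correlation), with -0.43 ± 0.11 for Robo4 and -0.37 ± 0.14 for Flt1. Of 10 bone and marrow stroma genes 0 passed (median -0.22; camera, limma adjusted p = 0.0348; adjusted p = 0.439 with an estimated correlation), with -0.59 ± 0.12 for the proteoglycan gene Bgn. Of 13 MHC genes the class II gene H2-Eb1 fell, by 0.99 ± 0.19, and 5 were lower when adjusted over the list alone (camera, limma adjusted p = 0.0348; adjusted p = 0.440 with an estimated correlation). B-lineage genes had a median of -0.55 over 7 members, of which Fcmr fell and 4 were lower when adjusted over the list alone. Camera did not call this list (limma adjusted p = 0.0576) and fry did (limma adjusted p = 0.0337). In the other direction, erythroid genes had a median of 0.35 with 8 of 10 positive (limma adjusted p = 0.068 by camera and 0.0267 by fry).

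The remaining liver lists past the threshold were higher by small amounts, and each lost its call with an estimated correlation. Replication-dependent histone genes had a median of 0.17 over 28 members (camera, limma adjusted p = 0.00962; adjusted p = 0.487 with an estimated correlation); H4c14 rose at least 1.36-fold and 27 did not pass. The histone list was higher still in heterozygous against wild-type liver (median 0.27, 28 of 28 positive; limma's camera, adjusted p = 3.36e-11; adjusted p = 0.239 with an estimated correlation). It was lower in homozygotes than in heterozygotes (median -0.16, 25 of 28 negative; limma's camera, adjusted p = 0.0295; adjusted p = 0.556 with an estimated correlation). Acute phase genes had a median of 0.09 over 23 members (camera, limma adjusted p = 0.0348; adjusted p = 0.487 with an estimated correlation); the serum amyloid gene Saa1 rose by 1.56 ± 0.26 and 22 did not pass. Genes of the ER stress and amino acid response had a median of 0.18 over 25 members (camera, limma adjusted p = 0.0195; adjusted p = 0.439 with an estimated correlation), and the member that passed, the lipoprotein receptor Vldlr, fell by 1.96 ± 0.39. For 26 proteasome genes, 0 of which passed, the median was 0.08 (camera, limma adjusted p = 0.0293; adjusted p = 0.439 with an estimated correlation), with 0.55 ± 0.11 for Psmd8 and 0.54 ± 0.19 for Psmd2. For 65 mitochondrial respiration genes, 0 of which passed, it was 0.13 (camera, limma adjusted p = 0.0121; adjusted p = 0.841 with an estimated correlation), with 0.47 ± 0.21 for Atp5e and 0.45 ± 0.15 for Atp5g2. In all, camera called 14 of 48 lists in liver, 6 higher and 8 lower, 0 with an estimated correlation, and fry called 9.

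The other liver comparisons asked whether 1 mutant copy alters the tissue and how homozygotes stand against it. In heterozygous against wild-type liver, on 1 BeadChip, limma called 0 features, with 846 at an unadjusted p under 0.05 where chance gives 587.2; the smallest limma adjusted p was 0.107. The median change of male-biased genes was 0.18 (limma's camera, adjusted p = 0.0248; adjusted p = 0.795 with an estimated correlation) and that of female-biased genes -0.13. Fatty acid synthesis genes were lower there too (median -0.31; limma's camera, adjusted p = 0.00214; adjusted p = 0.515 with an estimated correlation). So were the xenobiotic metabolism (-0.12; limma's camera, adjusted p = 0.0101), NRF2 target (-0.13; 0.024), stroma (-0.18; 0.015), housekeeping (-0.11; 0.012) and stellate (-0.42; 2.32e-05) lists. Camera called the p53 target (0.16; limma adjusted p = 0.0064), PPARA target (0.14; 0.0129), acute phase (0.07; 0.0308) and histone lists as higher. None of these calls stood with an estimated correlation, and fry called 0 lists. Against heterozygotes, homozygous liver differed in genes already named: Cyp4a12b was at least 14-fold higher (not above background in heterozygotes), Hsd3b5 rose by 3.56 ± 0.44 and Cyp4a12a by 3.25 ± 0.42, while Sult2a2 (-5.82 ± 0.55), A1bg (-5.10 ± 0.41) and Cyp2b13 (-4.30 ± 0.57) fell. The median change from heterozygotes to homozygotes was 1.52 for male-biased and -1.96 for female-biased genes. A1bg read 13.70 ± 0.32 in heterozygotes, 11.70 ± 1.02 in wild type and 8.60 ± 0.27 in homozygotes. By limma, 81 features passed, 41 higher and 40 lower in homozygotes. For liver homozygous vs heterozygous the count was 38 and 47 without heterozygous replicates 1 and 2, 46, 38 and 52 without homozygous replicates 1, 2 and 3, and 340 with array weights.

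In brain, the comparison of homozygotes with wild type called 1 feature of 14423 by limma, which was Mysm1 (log2 change -1.93 ± 0.09). At an unadjusted p under 0.05 there were 757 features, where chance gives 721.2, and 10.7% of features had groups that did not overlap, against 10% by chance. Against heterozygotes, which shared a BeadChip with the homozygotes, Mysm1 was again the 1 feature past the threshold (-1.26 ± 0.09; 892 at an unadjusted p under 0.05). Heterozygous against wild-type brain gave 0 features by limma, with 846 at an unadjusted p under 0.05. Xist read 9.01 ± 0.15 in wild-type and 9.08 ± 0.37 in homozygous brain, and Nnt 4.79 ± 0.13 and 5.17 ± 0.28 (limma adjusted p = 0.929). Within 1 fit of all 27 arrays, whose spread is shared with the other tissues, the Mysm1 call of both comparisons was lost. For homozygotes against heterozygotes, more features passed with the first residual component as a covariate, an alternative chosen after seeing the data.

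The lists that camera called in brain had medians between -0.32 and -0.06, and no member of the lists named here passed the test over all genes. Of 19 oligodendrocyte and myelin genes, 18 were negative, such as the myelin lipid enzyme Ugt8a (-0.47 ± 0.17) and the phosphodiesterase Enpp6 (-0.40 ± 0.15), and 0 passed adjusted over the list alone (median -0.27; camera, limma adjusted p = 7.77e-07; adjusted p = 0.914 with an estimated correlation). Cytosolic ribosomal protein genes had a median of -0.08 over 51 members, 2 of them lower when adjusted over the list alone (camera, limma adjusted p = 8.79e-05; adjusted p = 0.914 with an estimated correlation), with -0.41 ± 0.09 for Rps15 and -0.35 ± 0.08 for Rps4x. Interferon-stimulated genes had a median of -0.16 over 25 members (camera, limma adjusted p = 0.000753; adjusted p = 0.610 with an estimated correlation), with -0.28 ± 0.12 for Parp14 and a dim Tap1 at -0.36 ± 0.09. Of 12 MHC genes, 3 were lower when adjusted over the list alone (median -0.06; camera, limma adjusted p = 0.00999; adjusted p = 0.914 with an estimated correlation), with H2-Ab1 at -0.98 ± 0.18 and Cd74, the class II invariant chain, at -0.91 ± 0.15.

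Some lists of markers of other tissues and of brain regions had medians away from 0 in brain, with no call standing at an estimated correlation. Of 10 measured hepatocyte genes, 7 were negative (median -0.32; camera, limma adjusted p = 0.00323; adjusted p = 0.914 with an estimated correlation), with the apolipoprotein gene Apoa2 at -0.99 ± 0.31. Of 7 cerebellum genes, 6 were negative (median -0.29; camera, limma adjusted p = 0.0120; adjusted p = 0.914 with an estimated correlation), with the cerebellar transcription factor Zic1 at -0.54 ± 0.12 and Zic2 at -0.34 ± 0.17. With genes not above background at their bounds, the medians were -0.23 for hepatocyte and -0.2 for cerebellum genes. Among lists that camera did not call, medians were 0.52 for striatum genes (12 of 12 positive; limma adjusted p = 0.169), 0.67 for skeletal muscle genes (9 of 10 positive; limma adjusted p = 0.168) and -0.32 for hypothalamus and pituitary genes (12 of 13 negative; limma adjusted p = 0.0797). Choroid plexus genes had a median of 0.13 in homozygotes against wild type, and of -0.75 in heterozygotes (limma's camera, adjusted p = 0.000389; adjusted p = 0.863 with an estimated correlation). Against heterozygotes, homozygous brain stood at 0.96 for choroid plexus genes (limma's camera, adjusted p = 5.78e-05) and 0.85 for striatum genes (0.0185), with adjusted p = 0.760 for both with an estimated correlation. The brain arrays also differed within genotypes: 1 residual component held 50.9% of the variance left after genotype and set wild-type replicate 3, heterozygous replicate 1 and homozygous replicates 1 and 3 apart from the other arrays. Camera called 6 of 53 lists in brain, 0 with an estimated correlation, and fry called 0.

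In bone marrow, genes of B lymphocytes were far lower on the arrays labelled homozygous than in wild type. Vpreb3, a partner of the pre-B cell receptor, read 4.98 ± 0.56 against 9.10 ± 0.90 (mean log2 ± SD, n = 3 each; 17.3-fold, limma adjusted p = 0.00271). Vpreb3, Cd79b, Ly6d and Myl4 were each detected on 1 of the 3 arrays labelled homozygous, so their changes rest on signals hardly above background. The B cell receptor chain Cd79b was 11.3-fold lower (-3.50 ± 0.32; limma adjusted p = 0.00158), with 5.09 ± 0.40 against 8.60 ± 0.58. On none of the arrays labelled homozygous was Fcmr, the Fc receptor for IgM, Fcrla, an Fc receptor-like protein of B cells, Igll1, a surrogate light chain, or the B cell receptor regulator Cd72 detected above background. They fell at least 7.91-fold, 6.88-fold, 5.29-fold and 3.66-fold. The B cell coactivator Pou2af1 (-2.29 ± 0.33), the lymphoid progenitor marker Ly6d (-2.58 ± 0.25), the myosin light chain Myl4 (-3.34 ± 0.41) and the kinase Sbk1 (at least 3.38-fold) fell as well.

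Genes of platelets and their precursors rose on the same arrays: the integrin chain Itga2b by 1.79 ± 0.22 (7.31 ± 0.21 against 5.52 ± 0.28), von Willebrand factor Vwf by 1.89 ± 0.28, the platelet receptor Mpig6b by 1.88 ± 0.31, the platelet lipoxygenase Alox12 by 1.84 ± 0.33 and the G protein subunit Gnaz by 1.91 ± 0.22. Cdkn1a, the cell cycle inhibitor p21 and a target of p53, read 7.62 ± 0.02 on the arrays labelled homozygous against 5.45 ± 0.16 in wild type (4.48-fold, limma adjusted p = 0.00158). Its other measured probe read 0.48 and did not pass (limma adjusted p = 0.175). Myl9, a contractile myosin light chain, rose by 2.19 ± 0.29, the ion exchanger Slc24a3 by 1.94 ± 0.39, the vesicle protein Syt4 by 2.30 ± 0.46 and Cps1, a urea cycle enzyme of hepatocytes, by 2.48 ± 0.43.

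By limma, 127 of 11507 bone marrow features passed, 32 higher and 95 lower, all of them changed by at least 1.5-fold, and 107 were named genes. The groups did not overlap for 3558 features (30.9%, against 10% by chance), and the median of all features was -0.12. The share was already 26.4% between heterozygotes and wild type, where limma called 0 features (1080 at an unadjusted p under 0.05), and 15.1% between the arrays labelled homozygous and heterozygotes. The arrays labelled homozygous lay on a BeadChip of their own and 2 of them were dim. For bone marrow homozygous vs wild type with array brightness as a covariate, an alternative chosen after seeing the data, 0 features passed by limma (754 at an unadjusted p under 0.05): the median size of the 127 changes went from 1.48 to 1.28 and their median standard error from 0.25 to 0.37. Without homozygous replicate 2, whose Mysm1 signal was 4.88 and which carried liver transcripts, 3569 passed. That array was the brightest labelled homozygous, with a raw mean signal of 137.5. Those left, at 102.0 and 92.1, were dimmer than every wild-type array (136.2 to 228.4), so brightness went with the label there. The count was 41 without homozygous replicate 1 and 28, 20 and 15 without wild-type replicates 1, 2 and 3.

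**Figure D3:**
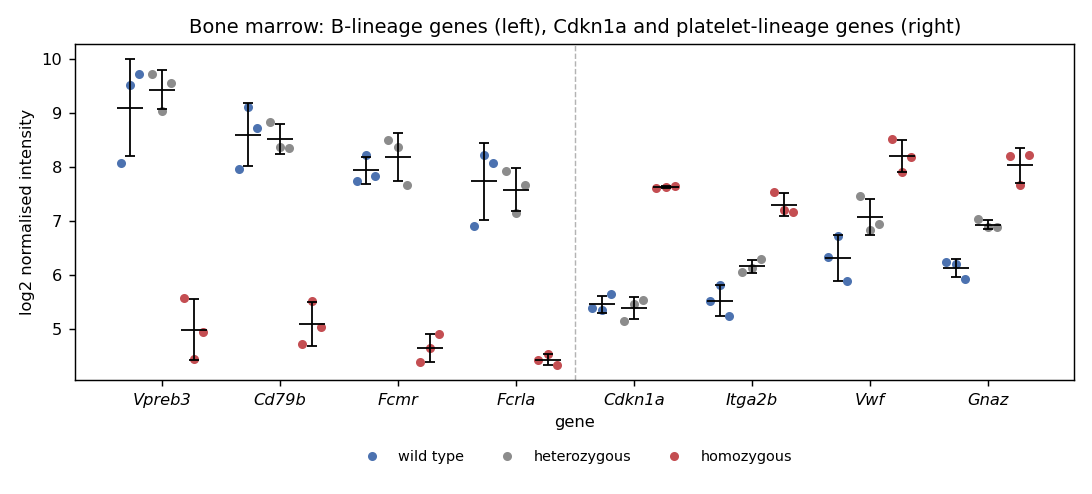
Log2 normalised intensity (vertical axis) on each bone marrow array for 4 B-lineage genes (left) and for Cdkn1a and 3 platelet-lineage genes (right), with mean and SD per labelled genotype (n = 3). Wild-type and heterozygous Fcmr means are 7.94 and 8.18 against 4.65 on arrays labelled homozygous, and Cdkn1a means are 5.45, 5.38 and 7.62.

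Of 17 measured B-lineage genes, 9 fell, 0 rose and 8 did not pass; adjusted over the list alone, 13 were lower and 1 higher (Rag2, a recombinase of lymphoid precursors, at 1.76, limma adjusted p over all genes 0.0888). The median was -1.94, or -1.30 with genes not above background at their bounds (camera, limma adjusted p = 1.93e-09; adjusted p = 0.393 with an estimated correlation). Of 18 megakaryocyte and platelet genes, 4 rose, 0 fell and 14 did not pass, while 14 were higher and 1 lower when adjusted over the list alone (median 1.43; camera, limma adjusted p = 1.85e-09; adjusted p = 0.393 with an estimated correlation). In heterozygous against wild-type marrow the medians of the B-lineage and platelet lists were -0.07 and 0.50 (platelet list by limma's camera, adjusted p = 0.0228; adjusted p = 0.862 with an estimated correlation). Cell cycle genes were negative for 23 of 23 members; the replication licensing factor Cdc6 fell by 1.43 ± 0.23, and 12 were lower when adjusted over the list alone (median -0.52; camera, limma adjusted p = 2.46e-05; adjusted p = 0.393 with an estimated correlation). Of 13 MHC genes, 4 fell: H2-Aa (-2.23 ± 0.26), Cd74 (-1.94 ± 0.31), which also stands in the B-lineage list, H2-Eb1 (-1.83 ± 0.27) and H2-Ab1 (-1.48 ± 0.26), the class II molecules of antigen-presenting cells. Adjusted over the list alone 6 were lower (camera, limma adjusted p = 4.49e-05; adjusted p = 0.393 with an estimated correlation).

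Other lists were lower on the bone marrow arrays labelled homozygous. Cytosolic ribosomal protein genes had a median of -0.49 over 50 members, of which Rpl36a fell by 1.19 ± 0.23 and 49 did not pass (camera, limma adjusted p = 2.74e-05; adjusted p = 0.601 with an estimated correlation). Replication-dependent histone genes had a median of -0.56 over 33 members, of which H3c1 (-1.60 ± 0.29) and H4c14 (-1.58 ± 0.23) fell (5 lower adjusted over the list alone; camera, limma adjusted p = 0.000172; adjusted p = 0.393 with an estimated correlation). Of 30 interferon-stimulated genes, Ifi27l2a fell by 2.27 ± 0.42 and 29 did not pass (4 lower and 1 higher adjusted over the list alone; median -0.51; camera, limma adjusted p = 0.00210; adjusted p = 0.393 with an estimated correlation). Of 21 erythroid genes, the red cell carbonic anhydrase Car1 fell by 2.01 ± 0.25 and 20 did not pass (4 lower adjusted over the list alone; median -0.47, against -0.39 in heterozygotes; camera, limma adjusted p = 0.00422; adjusted p = 0.560 with an estimated correlation). Of 26 histone H2A ubiquitination and Polycomb genes 0 passed (median -0.54; camera, limma adjusted p = 0.0274; adjusted p = 0.394 with an estimated correlation), with the H2A deubiquitinase Bap1 at -1.07 ± 0.31 and the demethylase Kdm2b at -0.84 ± 0.29.

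Lists that were higher there included 10 growth hormone and IGF genes (median 0.82; camera, limma adjusted p = 0.000131; adjusted p = 0.206 with an estimated correlation), of which the cytokine signalling inhibitor Socs2 rose by 1.71 ± 0.33 and 6 were higher when adjusted over the list alone. Neutrophil genes had a median of 0.36 over 24 members and 0 passed (camera, limma adjusted p = 0.00360; adjusted p = 0.394 with an estimated correlation), with 0.77 ± 0.24 for Lcn2 and 0.63 ± 0.24 for Cd177. The acute phase list, which shares Lcn2, had a median of 0.59 over 8 members and 0 passed (camera, limma adjusted p = 0.00809; adjusted p = 0.393 with an estimated correlation), with 0.78 ± 0.26 for haptoglobin Hp. Markers of other tissues moved as well. All 7 measured hepatocyte genes were positive, and Cps1 passed (median 1.72, or 1.54 with genes not above background at their bounds; camera, limma adjusted p = 0.00440; adjusted p = 0.393 with an estimated correlation). Of 7 astrocyte genes the gap junction gene Gja1 rose by 1.70 ± 0.30 (median 0.91; camera, limma adjusted p = 0.0274; adjusted p = 0.393 with an estimated correlation), and 5 adipocyte genes had a median of 0.82 with 0 past the test (camera, limma adjusted p = 0.0274; adjusted p = 0.393 with an estimated correlation), with Car3 at 1.38 ± 0.35 and adiponectin Adipoq at 0.82 ± 0.26. Liver transcripts stood out on 1 array, homozygous replicate 2, as genes chosen after their values were seen show. The liver protease inhibitor Serpina1b read 10.51 there against 4.87 and 4.78 on the other arrays labelled homozygous, the plasma carrier Ttr 10.04 against 5.22 and 4.73, and the urinary protein gene Mup2 13.78 against 7.17 and 5.76. The other 2 arrays labelled homozygous also lay above wild type for Mup2, which read 4.8, 4.49 and 4.6 there. Cps1 did not follow this, at 7.24, 6.78 and 7.84 on homozygous replicates 1, 2 and 3. Without homozygous replicate 2, the call of the B-lineage list (limma's camera, adjusted p = 0.000354), of the platelet list (1.26e-05) and of the cell cycle (0.00212), ribosomal protein (1.44e-06), MHC (0.00146) and growth hormone (0.01) lists stood. Without it the hepatocyte (limma's camera, adjusted p = 0.272), acute phase (0.272), erythroid (0.717), neutrophil (0.145), interferon-stimulated (0.145), histone (0.111), H2A ubiquitination (0.0727), astrocyte (0.217) and adipocyte (0.111) lists were not called.

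The p53 target list, which holds Cdkn1a, had a median of 0.14 with 14 of 19 members positive. Camera did not call it (limma adjusted p = 0.0597) and fry did (limma adjusted p = 0.00511). Camera called 15 of 51 lists in bone marrow, 7 higher and 8 lower, 0 with an estimated correlation, and fry called 16.

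**Figure D4:**
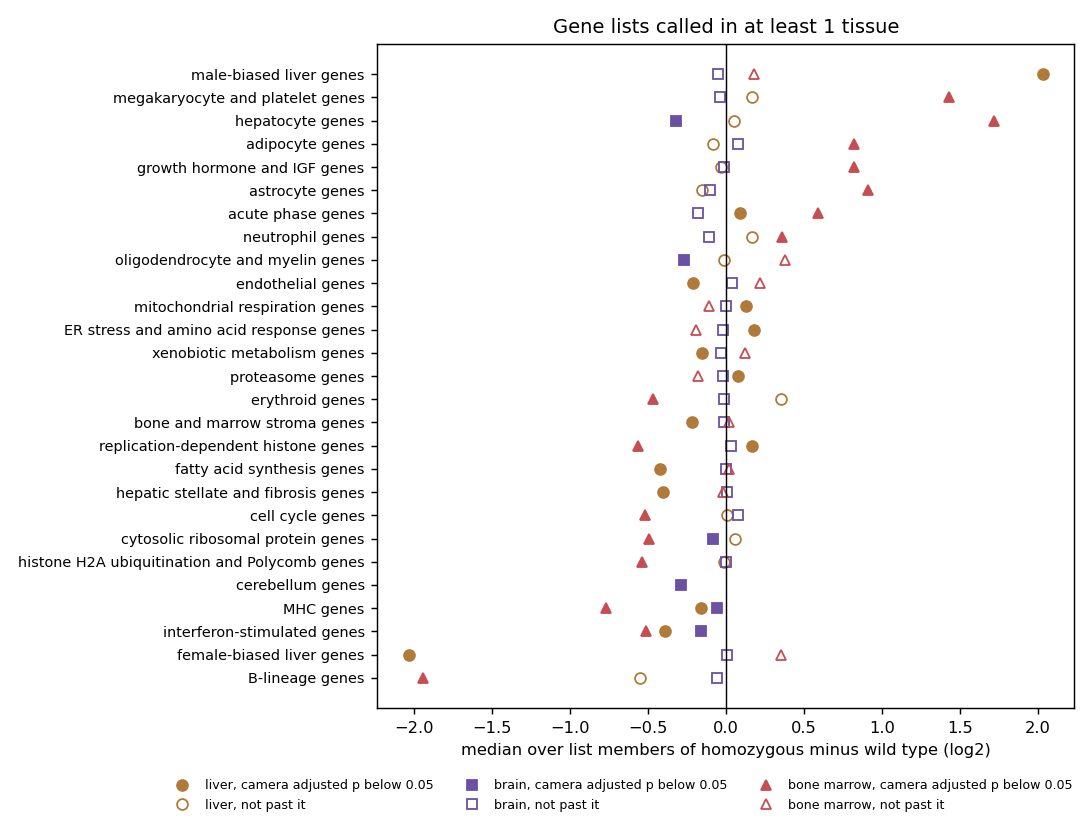
Median over measured members of the homozygous minus wild-type log2 difference (horizontal axis) for every list called by camera in at least 1 tissue (vertical axis), with filled symbols where camera's adjusted p was below 0.05 at the preset correlation. Male-biased genes stand at 2.03 in liver, and B-lineage genes at -1.94 in bone marrow arrays labelled homozygous.

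Against heterozygous bone marrow, the B-lineage list had a median of -1.67 on the arrays labelled homozygous, with genes not above background at their fitted values. Vpreb3 (-4.45 ± 0.44, 21.8-fold) and Myl4 (-3.78 ± 0.41) fell, and Fcmr fell at least 9.35-fold. Cdkn1a rose by 2.24 ± 0.20 (7.62 ± 0.02 against 5.38 ± 0.21), the protease inhibitor Stfa1 by 2.28 ± 0.31 and the carbonic anhydrase Car3, not above background in heterozygotes, by at least 4.03-fold. By limma, 77 features passed, 16 higher and 61 lower. For bone marrow homozygous vs heterozygous the count was 131 with array brightness as a covariate, chosen after seeing the data. It was 1585 without homozygous replicate 2, 24 without homozygous replicate 1, and 25, 26 and 27 without heterozygous replicates 1, 2 and 3. Heterozygous against wild-type marrow, on 1 BeadChip, gave 0 features by limma, with 1080 at an unadjusted p under 0.05 and a smallest limma adjusted p of 0.515. For bone marrow heterozygous vs wild type the count was 137 in a fit of those 6 arrays alone and 1324 with array weights. When changes of 1.5-fold between homozygotes and wild type were planted in simulated data, 1.8% were recovered in bone marrow, 41.6% in liver and 51.3% in brain.

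Whether the effect of the homozygous genotype differed between tissues was tested directly over all 27 arrays. Bone marrow minus liver differed for 2736 features (1246 higher, 1490 lower), among them the B cell receptor for BAFF Tnfrsf13c (-3.16 ± 0.21; -3.18 in marrow labelled homozygous and -0.02 in liver), Cd72 (-4.31 ± 0.36), the histone gene H4c14 (-3.81 ± 0.29) and, in the other direction, Sult2a2 (5.97 ± 0.48). Bone marrow minus brain differed for 1987 features (867 higher, 1120 lower), led by Tnfrsf13c (-3.17 ± 0.21), Fcrla (-5.03 ± 0.37), Sbk1 (-4.14 ± 0.31), the ribonuclease Rnase6 (-3.23 ± 0.26) and Fcmr (-4.61 ± 0.39). Liver minus brain differed for 26 features (13 higher, 13 lower), led by Sult2a2 (-5.96 ± 0.48), Cyp4a12a (4.65 ± 0.41), Mup20 (2.22 ± 0.28), Cyp2b13 (-3.92 ± 0.52) and Cyp4a12b (3.61 ± 0.49). None of these 5 was measured in brain, nor Sult2a2 in bone marrow, so these values restate the liver change. Tnfrsf13c, Cd72, Fcrla, Sbk1 and Fcmr were not above background on the bone marrow arrays labelled homozygous, so their values are fitted differences and not measured sizes; H4c14 and Rnase6 were detected on 1 of these 3 arrays. Scaling over all 27 arrays also made the marrow changes larger than the fit of bone marrow alone, at -2.89 against -1.58 for H4c14, -4.21 against -2.48 for Cd72 and -4.08 against -2.36 for Sbk1. These joint fits share 1 spread between tissues although bone marrow arrays scattered more. Random labelings that regrouped both tissues gave up to 1648 features for bone marrow minus liver (median 1). For bone marrow minus brain they gave up to 1635 (median 1.5), so counts of this order can arise without the real grouping. Over the arrays left out in turn, bone marrow minus liver ranged from 1477 (without bone marrow wild-type replicate 2) to 6297 (without bone marrow homozygous replicate 2), bone marrow minus brain from 1037 to 5583 for the same arrays, and liver minus brain from 16 (without brain wild-type replicate 2) to 28.

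The same genes were seldom called in more than 1 tissue. Among 9244 features tested in both liver and bone marrow, the IgM receptor Fcmr, the class II gene H2-Eb1 and Snn, a membrane protein, were lower in both, 3 where 0.441 would be shared by independent lists (exact hypergeometric p = 0.00966). That p-value takes genes as independent of each other and was not adjusted for the other tissue pairs and directions. In the other direction, 1 unnamed probe was higher in both. Mysm1 was the 1 feature shared by liver and brain. An effect common to the 3 tissues, with BeadChip as a term, was called for 0 features by limma, with 469 at an unadjusted p under 0.05. In this layout the BeadChip terms take up the homozygous liver and bone marrow arrays. The estimate then rests on heterozygous against wild type in liver and bone marrow and on homozygous against heterozygous in brain. Mysm1 stood at -1.62 ± 0.53 there and did not pass (limma adjusted p = 1). Without the BeadChip term the effect averaged over the 3 tissues passed for 4 genes, all of them lower. They were Mysm1 (-1.62 ± 0.30), the class II genes H2-Ab1 (-0.95 ± 0.14) and H2-Eb1 (-1.12 ± 0.18), and the X-linked ribosomal protein gene Rps4x (-0.47 ± 0.08). Such an average does not show a fall in each tissue: Mysm1 in bone marrow alone stood at -0.18 ± 0.43. With BeadChip in the model H2-Eb1 stood at -0.39 ± 0.27, H2-Ab1 at -0.67 ± 0.23 and Rps4x at -0.51 ± 0.17. The estimates with and without BeadChip rest on different arrays, so a smaller value does not show that BeadChip explains the fall.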

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

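Of the tests weighed here, those of male livers, of growth hormone output, of BeadChip for the sex-biased genes, of brightness for the B-lineage and platelet genes, of BeadChip for the B-lineage genes, of the 62 liver features not measured in brain, and of mislabelling and scaling for Mysm1 in bone marrow were chosen after the result was seen. The others were set before their results were seen, that with array signal as a covariate after the brightness of the arrays was known. The results came up because the test of the difference between tissues passed. For bone marrow minus liver 2736 features passed, with Tnfrsf13c (-3.16), Cd72 (-4.31), H4c14 (-3.81), Fgd6 (-2.76) and Sult2a2 (5.97) named. For bone marrow minus brain 1987 passed, with Tnfrsf13c (-3.17), Fcrla (-5.03), Sbk1 (-4.14), Rnase6 (-3.23) and Fcmr (-4.61). For liver minus brain 26 passed, with Sult2a2 (-5.96), Cyp4a12a (4.65), Mup20 (2.22), Cyp2b13 (-3.92) and Cyp4a12b (3.61). Tnfrsf13c, Cd72, Fgd6, Fcrla, Sbk1 and Fcmr were not above background on any bone marrow array labelled homozygous, so their values are fitted differences and not measured sizes. Sult2a2 was not measured in bone marrow, and none of the 5 genes of liver minus brain was measured in brain, so these values restate the liver change.

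These counts were set against 100 labelings of the homozygous and wild-type arrays within the tissues, the real one included. For bone marrow minus liver, 1 of 100 gave as many features, the real one (2736, highest other 2353). A chance labeling is unlikely there by this count, which was not adjusted for the other counts. For bone marrow minus brain 10 of 100 gave as many (1987, highest other 2403) and for liver minus brain 6 of 100 (26, highest other 28). A chance labeling cannot be excluded for these by this count. All 9 and all 5 other labelings with as many features kept the real split in 1 of the tissues. With both tissues regrouped the highest counts were 1635 and 0 for these, and 1648 for bone marrow minus liver. For the effect common to the 3 tissues 100 of 100 gave at least the real 0 by limma (469 at an unadjusted p under 0.05, highest other 1). Any labeling gives at least 0, so that count carries no information.

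Within a tissue, 3 arrays against 3 give 10 splits, too few for a share under 0.05. Where the real split gave 0 features, every split gives as many, so the number of splits carries no information there. As many features as the real split came from 1 split of 10 for homozygous against wild-type liver (167; highest other 0), 10 for heterozygous against wild-type liver (0 by limma, 846 at an unadjusted p under 0.05; highest other 9) and 1 for homozygous against heterozygous liver (81; highest other 4). In brain the numbers were 1 (1; highest other 0), 10 (0 by limma, 846 at an unadjusted p under 0.05; highest other 1) and 2 (1; highest other 1). In bone marrow they were 1 (127; highest other 0), 10 (0 by limma, 1080 at an unadjusted p under 0.05; highest other 0) and 2 (77; highest other 370). The split with 370 set heterozygous replicate 1 and homozygous replicates 1 and 3 against the other arrays. Their raw mean signals were 106.1, 102.0 and 92.1. Those of heterozygous replicates 2 and 3 and homozygous replicate 2 were 99.3, 134.7 and 137.5, and the last of these arrays carried liver transcripts. The split thus went in part with array brightness, and its source was not tested.

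The first pattern is the rise of male-biased and fall of female-biased genes in homozygous liver, for which a BeadChip difference stays open: 8 of the 25 called sex-biased genes were measured in brain, with a median shift in the liver direction of 0.01 (from -0.27 to 0.18) between wild type and heterozygotes, on 2 BeadChips, the first of them that of the homozygous livers, against 1.91 in liver. Over all 105 called features measured there the median shift was -0.03 (quartiles -0.14 and 0.08) against 0.87 in liver. This argues against a shift of the homozygous livers' BeadChip for these features, though wild type and heterozygotes also differ in genotype. The BeadChip of the wild-type livers held no brain array, so a shift of that BeadChip stays open for these features too. For the 62 features not measured in brain, a shift of either BeadChip stays open. Male livers among the homozygous arrays would lack Xist. The lowest array lay -0.88 from the wild-type mean and Kdm5d had 0 detections, which argues against male livers. The 1 detected Uty probe (4.72 against 4.89 in wild type) lay near background in liver and was detected on every brain array, so it does not bear on sex here. Lower growth hormone output would lower Igf1, Igfals, Socs2 and Cish together; their median of 0.04 (from -0.28 to 0.22) argues against that for these 4 genes alone, and since Igfbp3 of the same list fell by 0.59, lower output stays possible, as do a changed timing of growth hormone pulses or an androgen effect, of which the data hold no test.

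The second pattern is the loss of B-lineage and gain of platelet transcripts on bone marrow arrays labelled homozygous. Dim arrays could lower B-lineage genes, but heterozygous arrays, nearly as dim, had a median of -0.07 against wild type, which argues against array signal for these genes. For platelet genes heterozygous arrays stood at 0.50 against 1.43 on those labelled homozygous, both set against the same wild-type arrays, so brightness stays open for part of the rise, while 0.95 between homozygous and heterozygous arrays of similar brightness argues against it as the whole cause. With array signal as a covariate the median change of the 127 called features was 1.28 in size instead of 1.48 and the B-lineage median -1.6 instead of -1.94, though 0 features then passed by limma (754 at an unadjusted p under 0.05 for bone marrow homozygous vs wild type), with standard errors of 0.37 instead of 0.25. A BeadChip difference could not be tested, because 1 genotype lay on that BeadChip, and a loss of B-lineage cells may underlie their part of the pattern, since mixed tissue cannot separate cell number from expression per cell.

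The third pattern is Mysm1, which fell in liver and brain and not in bone marrow. In brain a BeadChip difference is argued against by the fall of 1.26 on the BeadChip that heterozygotes and homozygotes shared, out of a log2 change of -1.93 from wild type. If the bone marrow arrays with high Mysm1 were mislabelled wild type, their B-lineage medians could be near wild type; they lay at -1.71 and -2, but a BeadChip of their own could also lower these genes, and no other marrow array ties them to the genotype, so mislabelling stays open. Scaling of dim arrays may have raised a weak signal: before scaling, homozygous minus heterozygous was -0.58 (SE 0.49) on the log2 scale, which leaves it open. The array with low Mysm1 (4.88) also carried liver transcripts, so its value may not reflect bone marrow cells, a point these data cannot settle.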

How the results depend on the processing

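The alternatives with array signal, without the 4 dimmest arrays and with the brain residual component were chosen after seeing the brightness or the clusters of the arrays. Leaving out the 4 dimmest arrays leaves 3 wild-type, 1 heterozygous (replicate 3) and 1 homozygous bone marrow array (replicate 2, with liver transcripts), so its values say nothing about the stability of the other counts. For each value here the cause was not tested, except that fits of fewer arrays or of other features change what is counted. Counts are of features by limma.

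For liver homozygous vs wild type the count of 167 was 328 without background correction, 282 with the deposited values, 108 without a detection filter, 385 with array weights, 299 with trend and robust, and 46 (without homozygous replicate 2) to 120 with 1 array left out. For liver heterozygous vs wild type it was 2 with neqc over 27 arrays, 10 in 1 fit of 27 arrays, 1 without a detection filter and 0 to 1 with 1 array left out, highest without wild-type replicate 1. For liver homozygous vs heterozygous it was 150 without background correction, 340 with array weights and 38 (without heterozygous replicate 1) to 79 with 1 array left out.

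For brain homozygous vs wild type it was 2 without background correction, with neqc over 27 arrays, with every probe and with trend and robust, and 0 in 1 fit of 27 arrays. For brain homozygous vs heterozygous it was 0 in that fit, 2 with every probe and 16 with the residual component. Leaving out 1 array left 1 in each.

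For bone marrow homozygous vs wild type the count of 127 was 5256 in 1 fit of 27 arrays, 14 with the 6 arrays of the pair alone, 207 with stricter detection, 6589 with array weights, 0 with array signal as a covariate, 599 without the 4 dimmest arrays (1 array labelled homozygous left), and 15 (without wild-type replicate 3) to 3569 (without homozygous replicate 2) with 1 array left out. For bone marrow heterozygous vs wild type it was 2110 in 1 fit of 27 arrays, 137 with the pair alone, 1324 with array weights and 3 without the dimmest arrays. For bone marrow homozygous vs heterozygous it was 2786 in 1 fit, 23 with the pair alone, 118 with stricter detection, 2151 with array weights, 131 with array signal, 10 without the dimmest arrays (1 array against 1), and 24 (without homozygous replicate 1) to 1585 (without homozygous replicate 2) with 1 array left out.

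With array weights, bone marrow minus liver in homozygous vs wild type gave 5941, bone marrow minus brain in homozygous vs wild type 6037 and liver minus brain in homozygous vs wild type 371. With 1 array left out they gave 1477 to 6297, 1037 to 5583 and 16 to 28. Bone marrow wild-type replicate 2 set the lowest and bone marrow homozygous replicate 2 the highest of the first 2 ranges, and brain wild-type replicate 2 the lowest of the last. The shared effect gave 1 with array weights and 4 without the BeadChip term. List calls by limma's camera fell to 0 in each tissue with an estimated correlation, fry called 9 in liver and 0 in brain, and no detection filter left 2 in brain. With 1 array left out the list calls ran from 11 to 16 in liver, 5 to 10 in brain and 6 (without homozygous replicate 2) to 20 in bone marrow.

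Values that changed sign were not called. Eif2s3y in liver was -0.02 with array weights and -0.06 (without wild-type replicate 1) to 0.09 with 1 array left out. Xist was -0.38 to 0.29 (without homozygous replicate 2) in liver, and -0.14 (without homozygous replicate 3) to 0.19 in brain, with -0.01 without wild-type replicate 1. Mysm1 in bone marrow with array weights was 0.20 for homozygous against wild type, 0.03 for heterozygous against wild type and 0.17 for homozygous against heterozygous. With 1 array left out, Mysm1 in bone marrow homozygous vs wild type ran from -0.63 to 0.43 (without homozygous replicate 2), Mysm1 in bone marrow heterozygous vs wild type from -0.08 to 0.06 (without heterozygous replicate 2; 0.02 without wild-type replicate 3) and Mysm1 in bone marrow homozygous vs heterozygous from -0.60 to 0.46 (without homozygous replicate 2). For heterozygous against wild type it was 0.07 without the dimmest arrays.

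Arrays of different genotypes share replicate numbers. After removing group means, 3, 5 and 2 of 9 same-number pairs in liver, brain and bone marrow correlated above 0.1, and 1, 0 and 0 arrays correlated best with their own number, so the numbers were not taken as pairs. A replicate block gave 82 and 45 for homozygotes against wild type and against heterozygotes in liver, 19 and 40 in bone marrow, and 2660, 1915 and 23 for bone marrow minus liver in homozygous vs wild type, bone marrow minus brain in homozygous vs wild type and liver minus brain in homozygous vs wild type. In bone marrow 24.8% of probes were detected on arrays labelled homozygous. There 2-fold changes were recovered in 22.5% of simulated cases, which drew on the scatter of the marrow arrays. Whether weak signal or uneven arrays set this limit was not tested.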

Other observations

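In homozygous liver, genes of lists that camera did not call changed as well; the genes in this part were chosen after their values were seen, while the tests were not. The early growth response factor Egr1 rose by 1.91 ± 0.31 (10.91 ± 0.58 against 9 ± 0.49, mean log2 ± SD, n = 3; limma adjusted p = 0.0187). Most of its immediate early list went the other way: 9 of 12 members were negative, 6 were lower when adjusted over the list alone, and the median was -0.30 (limma's camera, adjusted p = 0.0610). The heme synthesis enzyme Alas2 rose by 1.55 ± 0.26 (limma adjusted p = 0.0216). The lipase inhibitor Angptl4 (1.29 ± 0.20), the growth factor receptor Egfr (1.28 ± 0.21) and the innate immune receptor Nlrp12 (1.41 ± 0.21) rose. Of 23 measured genes near Mysm1 on chromosome 4, the complement genes C8a (1.12 ± 0.18) and C8b (1.44 ± 0.21) rose, 0 fell and 21 did not pass. The bile acid and drug transporter Slco1a4 (-1.27 ± 0.21) and the growth factor carrier Igfbp3 (-0.59 ± 0.11) fell. The IgM receptor Fcmr, not above background in homozygous liver, fell at least 2.18-fold (limma adjusted p = 0.00173).

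On bone marrow arrays labelled homozygous, the monocyte and macrophage genes Mpeg1 (-2.19 ± 0.28), F13a1 (-1.51 ± 0.24) and Ly86 (-1.23 ± 0.24) fell, 0 of the 18 measured rose and 15 did not pass; the list was not called (limma's camera, adjusted p = 0.0635). The plasma cell chaperone Mzb1 (-1.88 ± 0.37) and the T cell adhesion molecule Cd2 (-1.26 ± 0.26) fell, and the iron regulator Erfe rose by 1.77 ± 0.35. No explanation was tested for any of these genes.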
